A study of Mus musculus with 2 samples.

How the data were processed

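H3K4me1 ChIP-seq of lung from mouse embryos (strain B6NCrl, embryonic day 16.5) was represented by 2 biological replicates of 1 group, each with 2 technical replicates that the authors had combined, per the labels. Each replicate was a pool of embryos of both sexes. The 4 deposited peak lists were analysed: 1 for each replicate, 1 called on both replicates together (the pooled list) and 1 of replicated peaks, which the accompanying text files derive from the other 3 by a rule that is not given in the sources used here. Every peak of the replicated list was also a peak of the pooled list. The assembly is mm10, per the labels. The aligner, the peak caller, the control and the thresholds are not given in the sources used here, and no peak had a −log10 p below 2.

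Each list is in narrowPeak format, per the text files deposited with them. For each peak the authors deposited a signal value, a −log10 p, a −log10 q, a display score and the distance in bp from the peak start to its summit. The deposited signal value was planned to be read as a fold enrichment, but the files do not state that it is a fold over a control, so it is called signal here and was used to describe and rank peaks within a list and, in 1 correlation, across the peaks of both replicates. The deposited score and the summit distance were not used. No columns of values from unmapped samples were present (0 columns). The lists hold no read counts, so neither sequencing depth nor coverage in reads is known, and the Wilson 95% intervals given for shares cover counting error only.

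Analyses were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap of replicates was also computed with bedtools 2.31.1 coverage, which gave identical counts. Gene models were those of GENCODE release M21 on GRCm38 patch 6, and sequence was taken from the reference of that build, whose chromosome lengths are those of mm10. Autosomes and chromosome X were used, 20 chromosomes in all. The 21646 protein-coding genes on them were each represented by the start of 1 protein-coding transcript. It was chosen by the annotation's principal isoform rank, then by membership of its basic set, then as the longest. Promoters in the assignment of peak centres used the starts of all protein-coding transcripts.

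A peak counted as found in the other replicate when at least 50% of its length lay in the merged peaks of that replicate. The level without alignment of the lists was the mean over 20 circular shifts of the other list within each chromosome. Overlap was recomputed between equal numbers of peaks, taking from each list the peaks of lowest p up to the length of the shorter list. Each replicated peak that overlapped both replicates was given the highest signal value of each, for a Spearman correlation across peaks. Peak centres were assigned to promoters (within 1 kb of a protein-coding start site), exons, introns or intergenic sequence and compared with the share of the genome without gaps. Start sites covered by a peak were counted in steps of 100 bp up to 5 kb either side, and the dip was the percent at the start site minus the highest percent within 3 kb. CpG-rich promoters had an observed over expected CpG of at least 0.6 and a GC content of at least 50% within 500 bp of the start site.

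Window coverage was the percent of the sequence within 50 kb of a start site that peaks covered. For 21 gene lists (8 of lung cell types, 2 of blood cells in the tissue, 7 of other tissues, signalling targets, housekeeping genes, and anterior and posterior Hox genes) the median was placed among 10000 random lists of the same size, matched gene by gene on quintiles of gene length and of the number of start sites in the window. A percentile of 95 or more was called. The percentile describes these libraries and is not a test over replicates. The symbol Ahsp matched no gene model and was left out, and Tf was matched to Trf through RefSeq synonyms. Sftpc and Lgi3, Krt15 and Krt19, Olig1 and Olig2, Alb and Afp, and neighbouring Hox genes share most of their windows. Sftpd and Sftpa1, and Tbx2 and Tbx4, share a part of theirs. Promoter peaks lay within 2.5 kb of a start site. Domains were made by joining replicated peaks at most 1 kb apart.

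Consensus sequences of 17 transcription factor families were counted on both strands in distal replicated peaks and in control windows. Distal peaks had their centre over 1 kb from any protein-coding start site, so a wide one can still reach a start site. Control windows had the same width and lay 10 kb away outside every pooled peak. They were weighted to the same GC content in bins of 2 percentage points. Intervals of the ratio came from 200 resamplings of peaks and windows. Each consensus was also counted without soft-masked bases, and set against 20 rearrangements of its letters with the same number of CG pairs. For chromosome X, windows of 100 kb with at least 90% known sequence were compared with autosomal windows of the same number of start sites (4 or more as 1 class) and the same share of soft-masked repeats (bins of 5 percentage points with at least 20 autosomal windows), with intervals from 1000 resamplings of windows. For the comparison of replicates by gene list, the share of replicate 1 peaks that overlapped replicate 2 by at least 1 bp was used. It was set against the share predicted from 20 classes of p and 10 classes of width.

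The genes named were fixed by rule: for each list the 3 members with the highest and the 1 with the lowest window coverage, any other member of a list, the 20 genes with the highest coverage of the genome (a gene within 100 kb of a higher one was skipped), the nearest genes of the 10 widest domains, and the 5 peaks of highest signal value. The gene lists, the consensus sequences, this rule, the tests and the alternatives listed below were set before the data were examined. Exceptions are those named in the closing part as later choices or as tests of patterns already found.

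The procedures were tested on simulated data. A made overlap of 59.6% over 10000 peaks was recovered as 59.6%, and a made dip of −40.7 points over 5000 start sites as −40.7. Of 200 random gene lists, 7 reached the 95th percentile, and lists raised 2-fold and 3-fold in coverage were found in 104 and 149 of 200 cases. A list that did not reach it is therefore not shown to lack the mark. The simulated genes were evenly spaced, with coverage drawn independently of gene length and of neighbours. These rates therefore do not test the matching or the effect of shared windows in the real lists. A motif added at 2 per kb to 700 windows was recovered at 2.00 per kb, and the median ratio of 20 rearrangements not added was 0.991.

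Alternatives tried were an overlap of 1 bp or 90%, peaks with q at or below 0.001, ranking by signal value, the top 20000 peaks, −log10 p or autosomes alone in the correlation, promoters within 2.5 kb or 1 kb, gene windows of 10 kb and 100 kb, random lists of any genes, joining distances of 200 bp and 3 kb, controls 50 kb away or not matched on GC, the pooled list, and each replicate's own list in place of the replicated list.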

Results

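The monomethylated form of lysine 4 on histone H3 (H3K4me1), which is known to mark enhancers and the flanks of active promoters, was profiled by ChIP-seq in the lung of mouse embryos at embryonic day 16.5. At this age the airways are still branching, and the epithelium at their tips begins to give rise to the cells that will line the alveoli. The series held 1 group with 2 biological replicates of strain B6NCrl. Each replicate was a pool of male and female embryos. Replicate 2 came from 41 embryos, and the labels gave no number for replicate 1. With 1 group there was no contrast between conditions, so the replicates were compared with each other and the peaks with the genome, its genes and its sequence.

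The authors called peaks in each replicate and on both replicates together, and gave a further list of replicated peaks. Replicate 1 held 178593 peaks with a median width of 321 bp that covered 81.7 Mb (3.19% of the genome without gaps). Replicate 2 held 85926 peaks with a median width of 270 bp that covered 29.6 Mb (1.16%). The pooled list held 143232 peaks (2.70% of the genome), and the replicated list held 99129 peaks with a median width of 442 bp (2.27%). Unless another list is named, a peak is a replicated peak. The lists hold no read counts, so the sequencing depth behind them is unknown. The signal value of a peak is the authors' own value for that peak and was not stated to be a fold over a control. Shares of peaks or genes are given with Wilson 95% intervals, which cover counting error only. Peaks and genes are not independent replicates, so no p-value was computed over them. Coordinates are on mm10 and count from 1.

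The regions most densely covered by H3K4me1 peaks carried them in both replicates. The window from 50 kb upstream to 50 kb downstream of the start site of Nfix, a transcription factor of the nuclear factor I family, was covered for 50.05% by peaks of replicate 1 and for 30.7% by peaks of replicate 2. Around Rara, which encodes retinoic acid receptor alpha, the window was covered for 47.5% in replicate 1 and 30.0% in replicate 2. Around Vgll4, a cofactor of the TEAD transcription factors, it was covered for 49.6% and 29.8%. The median gene had 3.72% of its window covered in replicate 1 and 1.27% in replicate 2.

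Most peaks of replicate 2 were found again in replicate 1, and most peaks of replicate 1 were not found in replicate 2. Of the 85926 peaks of replicate 2, 68580 (79.8%, 95% interval 79.5 to 80.1) had at least 50% of their length inside peaks of replicate 1. Circular shifts of the other list along each chromosome gave a mean of 3.34% over 20 draws. In the other direction 37160 of 178593 peaks (20.8%, 20.6 to 20.996) were found, against 1.11% after shifts. Each list was divided into 10 equal classes by the authors' −log10 p. In the strongest class, 98.3% of the peaks of replicate 2 and 57.8% of those of replicate 1 were found in the other list. The shares were 58.8% and 7.38% in the weakest class. Between equal numbers of top peaks, 85926 from each list, 64.0% of the peaks of replicate 2 and 31.6% of those of replicate 1 were found. Width was not matched, and the strongest class had a median of 902 bp in replicate 1 and 545 bp in replicate 2, so a rule on the share of length favours replicate 2. With any overlap, 86.9% of the strongest class of replicate 1 and 99.2% of that of replicate 2 were found. Across the 59353 replicated peaks that overlapped a peak in both replicates, the highest signal values of the replicates had a Spearman correlation of 0.353. The share of replicate 1 depended on how a shared peak was defined. It was 35.2% with an overlap of 1 bp, 3.77% with 90% of the length, and 3.81% when both lists held only peaks with q at or below 0.001 (117207 peaks of replicate 1 and 8552 of replicate 2).

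The replicated list followed replicate 1 more closely than replicate 2. At least 50% of the length was covered in replicate 1 for 95.9% of replicated peaks (95.7 to 96.0) and in replicate 2 for 44.1% (43.8 to 44.4). No peak of replicate 2 overlapped 38205 of them (38.5%). Both replicates covered at least 50% of the length of 41366 replicated peaks.

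**Figure D1:**
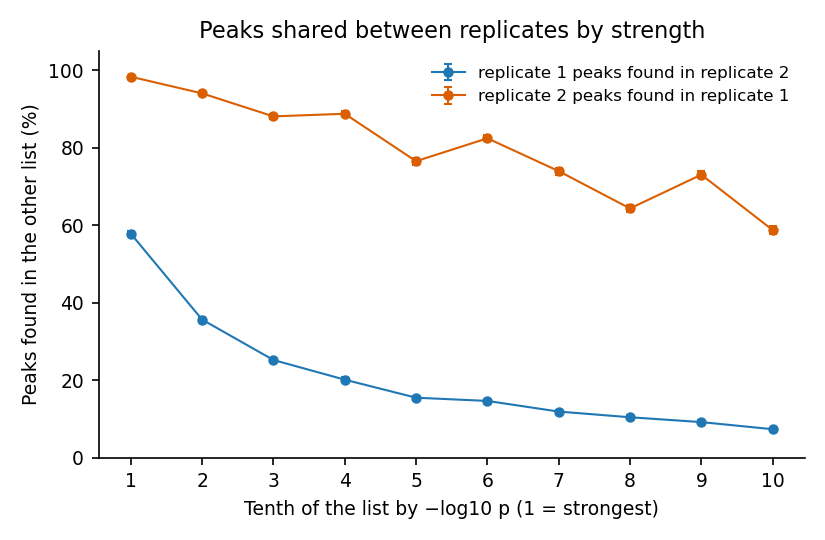
The share of peaks with at least 50% of their length inside peaks of the other replicate (vertical axis, percent) is plotted for each of 10 equal classes of a list ranked by the authors' −log10 p (horizontal axis, 1 is the strongest), with blue points for replicate 1, orange points for replicate 2 and bars for Wilson 95% intervals. Replicate 2 falls from 98.3% to 58.8%, and replicate 1 from 57.8% to 7.38%.

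H3K4me1 peaks were concentrated at promoters and inside genes. Peak centres within 1 kb of the start site of a protein-coding gene numbered 14946 (15.1%, 14.9 to 15.3), where 2.503% of the genome lies, a 6.02-fold excess. The excess was 4.89-fold with the peaks of replicate 1 and 5.85-fold with those of replicate 2. Introns held 50900 peak centres (51.3%, 51.0 to 51.7), 1.42-fold over their share of the genome, and exons held 3341 (3.37%), 1.40-fold. Intergenic sequence makes up 58.9% of the genome and held 29942 peak centres (30.2%, 29.9 to 30.5), 0.513-fold. Promoter peaks had a median signal value of 3.81, intron peaks 3.66 and intergenic peaks 3.598.

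At CpG-rich promoters the mark flanked the start site, and at CpG-poor promoters the start site differed less from its flanks. A peak covered 6.93% of the start sites of 21646 protein-coding genes, 16.2% of the positions at −600 bp and 26.2% of those at 1100 bp into the gene. The start site therefore lay −19.3 percentage points from the highest flank, −20.3 points with the peaks of replicate 1 and −11.5 points with those of replicate 2. The dip was −11.9 points with only the replicated peaks covered in both replicates. At the 10056 CpG-rich promoters, the kind found at housekeeping and many developmental genes, 5.24% of start sites and 44.6% of the positions at 1100 bp were covered, a dip of −39.4 points (−42.5 with the peaks of replicate 1, −23.2 with those of replicate 2 and −23.9 with peaks covered in both replicates). At the 11590 CpG-poor promoters, the kind found at many tissue-restricted genes, 8.39% of start sites were covered against at most 11.7% of a flanking position at 800 bp, a difference of −3.31 points from the highest of many positions. Coverage of these start sites was above that at −1 kb (5.10%) and at 5 kb upstream (2.64%) and downstream (3.44%).

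Of the 21646 genes, 13052 (60.3%) had a peak within 2.5 kb of the start site, among them Shh, the epithelial hedgehog ligand, Foxj1, the regulator of motile cilia, and Sftpc, which encodes surfactant protein C. The share was 67.1% in replicate 1 and 52.9% in replicate 2. It was 90.7% for CpG-rich and 33.9% for CpG-poor promoters. Nkx2-1, the homeodomain factor that specifies lung epithelium, had a peak that close in both replicates' own lists and none in the replicated list. Fgf10, the mesenchymal growth factor that drives branching, had one in replicate 1 alone, and Krt5, a keratin of basal cells, had none in the replicated list or either replicate.

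**Figure D2:**
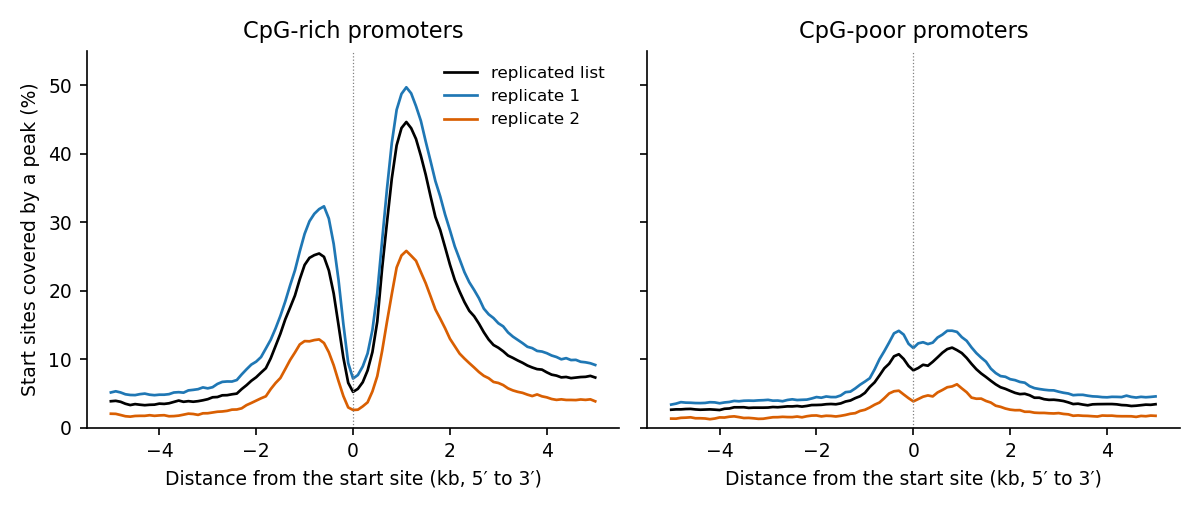
The percent of start sites covered by a peak (vertical axis) is plotted against the distance from the start site in kb, with gene direction from left to right (horizontal axis), for CpG-rich promoters on the left and CpG-poor promoters on the right, with a black line for the replicated list, blue for replicate 1 and orange for replicate 2. In the replicated list CpG-rich promoters fall from 44.6% at 1100 bp to 5.24% at the start site, and CpG-poor promoters from 11.7% at 800 bp to 8.39%.

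Genes of alveolar type 2 cells lay in regions with more H3K4me1 than matched random genes. The list for alveolar type 2 cells, which make surfactant, had a median window coverage of 9.89% over its 14 genes, against a median of 2.35% for random lists, and no more than 5.92% at the top of their 95% range. It was 12.4% with the peaks of replicate 1 and 4.00% with those of replicate 2, against 3.52% and 1.18% for random lists. With peaks covered in both replicates it was 2.69% (percentile 96.6), inside the 95% range, whose top was 2.86%. Muc1, a mucin of the apical membrane (19.3%), Dlk1, a Notch ligand homolog (19.3%), and Cebpa, a transcription factor of type 2 cell differentiation (14.9%), were highest. Sftpc reached 11.3% and Sftpb, which encodes surfactant protein B, 10.2%. No replicated peak lay in the window of Lamp3, a marker of lamellar bodies, which was covered for 0.356% in replicate 1, with a promoter peak there, and not in replicate 2. Around the 18 genes of progenitors at the branching tips the median was 4.68% against 1.04% for random lists, with Fgfr2, the epithelial receptor for Fgf10, at 21.9%, Id2 at 9.60% and the FGF-responsive factor Etv5 at 8.79%. Nkx2-1 was lowest at 0.362%, with 1.40% in replicate 1 and 0.912% in replicate 2.

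Alveolar type 1 genes, of the thin cells of gas exchange, had a median of 4.23% over 13 genes against 1.63% for random lists. Ager, the receptor for advanced glycation end products (17.6%), Vegfa (16.5%) and Hopx (15.6%) were highest and Sema3e was lowest (1.73%). The 14 airway genes had a median of 2.68% against 1.53% for random lists. Tppp3, a marker of ciliated cells, reached 19.2%, and the club cell genes Scgb1a1 and Cyp2f2 reached 9.89% and 7.77%. The windows of Krt5, of the basal cell factor Trp63 and of the secretory gene Scgb3a2 held no replicated peak. Krt5 had none in either replicate, Trp63 was covered for 1.34% in replicate 1, with a promoter peak there, and 0.180% in replicate 2, and Scgb3a2 for 0.207% in replicate 1 alone.

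Among the stromal and vascular lists, smooth muscle and pericyte genes had a median of 5.83% over 14 genes against 2.67% for random lists. Cspg4, a marker of pericytes (11.8%), Des, the muscle intermediate filament (9.75%), and the actin-binding Tagln (8.83%) were highest, and the cardiac and smooth muscle coactivator Myocd was lowest (3.82%). Mesenchymal genes had a median of 4.21% over 20 genes against 1.72%, from 29.1% around the hedgehog receptor Ptch1, 17.0% around Tbx2 and 13.0% around the collagen gene Col1a1 to no replicated peak around Fgf10 (1.51% in replicate 1 and 0.204% in replicate 2). Endothelial genes had a median of 3.42% over 16 genes against 2.26%, with Eng, a TGF-beta coreceptor, at 22.7%, Egfl7 at 20.3%, Esam at 12.2% and Emcn lowest at 0.217%. Mesothelial genes had a median of 3.79% over 10 genes against 2.84%. Msln reached 9.86%, Rspo1 6.42% and Upk1b 5.23%, and no replicated peak lay around Gpm6a, nor any in either replicate.

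Among 10000 random lists of the same size, matched on gene length and on the number of start sites in the window, 5 of the 8 lung lists lay at or above the 95th percentile. Alveolar type 2 lay at percentile 100, branching tip at 99.9, mesenchyme at 98.7, smooth muscle and pericyte at 97.9 and alveolar type 1 at 96.2. Endothelium lay at 83.4, airway at 82.0 and mesothelium at 72.9 (42.9 with the peaks of replicate 2 and 49.3 with peaks covered in both replicates). Against random lists of any genes, alveolar type 2 and smooth muscle remained above the 95th percentile, and branching tip (93.6), mesenchyme (89.7) and alveolar type 1 (84.3) did not. Lists rotated along the gene order keep neighbours together but are not matched on gene length or start sites. They put branching tip at 92.0, mesenchyme at 88.3 and type 1 at 84.2, and kept alveolar type 2 and smooth muscle above 95. For branching tip their median was 2.56%, near the 2.54% of random lists of any genes and above the 1.04% of matched lists. They therefore cannot separate an effect of neighbours from the loss of matching. With peaks covered in both replicates, smooth muscle lay at 94.6 and type 1 at 93.1. Airway genes reached 95.1 with the peaks of replicate 1 and 67.0 with those of replicate 2, endothelium 96.4 within 10 kb, and type 1 genes 84.2 within 100 kb, where airway lay at 36.5 and mesothelium at 31.8.

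**Figure D3:**
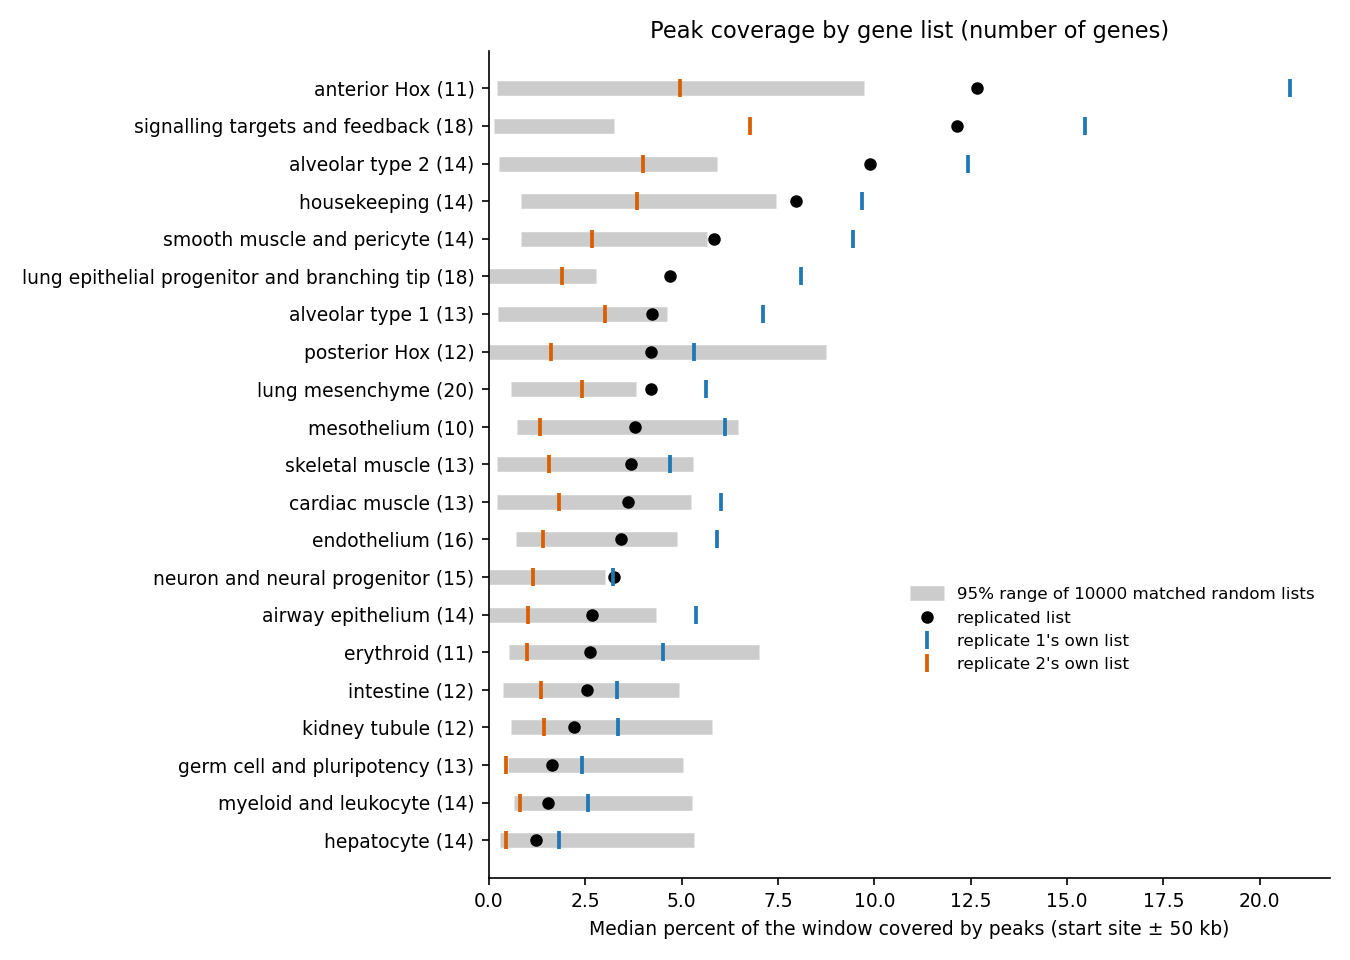
For each of the 21 gene lists, with its number of genes in brackets, the median percent of the window around the start site covered by peaks (horizontal axis) is shown as a black dot for the replicated list and as blue and orange bars for the lists of replicate 1 and replicate 2, over a grey bar for the 95% range of 10000 matched random lists scored on the replicated list. The black dots of 8 lists lie beyond their grey bars: anterior Hox (12.7%), signalling targets (12.1%), alveolar type 2 (9.89%), housekeeping (7.97%), smooth muscle and pericyte (5.83%), branching tip (4.68%), mesenchyme (4.21%) and neural (3.23%). Hepatocyte (1.21%) is lowest.

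Promoter peaks were counted in the lists of lung cells and of other tissues, and the difference between them was not tested. Over the 8 lung lists, 86 of 119 genes (72.3%) had a peak within 2.5 kb of the start site, and over the 7 lists of other tissues 37 of 92 (40.2%), beside 60.3% of all genes. Replicate 1 gave 88.2% and 48.9%, and replicate 2 gave 60.5% and 33.7%. With only the replicated peaks covered in both replicates the shares were 47.1% and 20.7%. By list, the lung counts were 14 of 18 for branching tip, 11 of 14 for alveolar type 2, 11 of 13 for type 1, 9 of 14 for airway, 12 of 20 for mesenchyme, 10 of 14 for smooth muscle, 12 of 16 for endothelium and 7 of 10 for mesothelium. With peaks covered in both replicates they were, in the same order, 9, 8, 7, 7, 7, 7, 8 and 3. The count for type 1 was 7 with the peaks of replicate 2 and that for mesenchyme 18 with the peaks of replicate 1. Among other tissues the neural list, with 13 of 15, lay above every lung list, and the cardiac list held 8 of 13. With the peaks of replicate 1 the neural list held 13 of 15, below branching tip (18 of 18) and alveolar type 2 (14 of 14). None of these counts was matched on CpG class, and 90.7% of CpG-rich and 33.9% of CpG-poor promoters had a peak. In the lung lists, in the order above, CpG-rich promoters numbered 13, 4, 6, 4, 8, 2, 4 and 4. They numbered 12 of 15 in neural, 0 of 14 in hepatocyte, 4 of 13 in cardiac and 2 of 13 in skeletal muscle genes. Germ cell genes held 6 of 13, intestinal and kidney genes 2 of 12 each, and housekeeping genes 12 of 14. Marked promoters did not follow CpG class in every list. Smooth muscle had 2 CpG-rich and 10 marked promoters, and germ cell genes had 6 and 2.

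Hepatocyte genes had the lowest median window coverage of all lists with replicated peaks, 1.21% (percentile 15.7), and 2 of 14 had a promoter peak. Germ cell and pluripotency genes lay lower with the peaks of replicate 2 (0.432% against 0.441%) and with q at or below 0.001 (0.747% against 0.772%). They also lay lower with peaks covered in both replicates (0% against 0.5615%). Albumin (Alb) lay at 0.589% and alpha-fetoprotein (Afp), whose window mostly overlaps that of Alb, at 0.217%. Serpina1a had no peak in its window in the replicated list or either replicate, and Cyp2e1 had 0.181% in replicate 2 alone. The highest were the haemopexin gene Hpx (11.03%), the prothrombin gene F2 (3.07%) and Apoa1 (2.42%). Germ cell and pluripotency genes had a median of 1.63% (percentile 30.4), with 2 of 13 promoters marked. The percentile was 8.11 with the peaks of replicate 2 and 3.01 with peaks covered in both replicates, where the median was 0%, 8 windows held no peak and no promoter was marked. Tdrd1 (8.44%), Pou5f1 (5.45%) and Rnf17 (3.90%) were highest. Zfp42 had no peak in the replicated list or either replicate and Tex101 had 1.41% in replicate 1 alone. Kidney tubule genes had a median of 2.21% (percentile 38.7), with 4 of 12 promoters marked (6 with the peaks of replicate 1 and 2 with peaks covered in both replicates), with Slc12a3 at 10.2%, Slc34a1 at 5.29%, Pax2 at 5.27% and no replicated peak at Umod (0.195% in replicate 1). Intestinal genes had a median of 2.55% (percentile 65.9), with 2 of 12 promoters marked and with Cdx1 at 7.91%, Olfm4 at 4.00%, Vil1 at 3.73% and no peak at Isx in the replicated list or either replicate. These percentiles depended on the window: within 10 kb and 100 kb they were 5.47 and 9.26 for hepatocyte, 21.7 and 68.9 for germ cell, 14.9 and 57.7 for kidney and 5.64 and 34.6 for intestinal genes.

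The muscle lists lay higher. Cardiac genes had a median of 3.61% (percentile 85.9) and 8 of 13 marked promoters (10 with the peaks of replicate 1, 5 with those of replicate 2 and 1 with peaks covered in both replicates), from 10.01% around Myl3, 8.03% around Tnni3 and 6.80% around Myl7 to 0.390% around Actn2. Skeletal muscle genes had a median of 3.68% (percentile 87.2, and 57.0 within 10 kb) and 6 of 13 marked promoters. The myoblast fusion gene Mymk (18.4%), Tnni2 (17.5%) and Chrna1 (9.88%) were highest and Myf5 had no replicated peak (0.231% in replicate 1). Neural genes had a median of 3.23% against 0.986% for random lists (percentile 98.2), and 13 of 15 promoters were marked. Gad1, which makes the transmitter GABA, lay at 4.95%, Sox1 at 4.42% and Nkx2-2 at 3.87%, and Slc17a6 had no peak in the replicated list or either replicate. This percentile was 99.8 within 10 kb and 96.2 with peaks covered in both replicates. It was below 95 with the peaks of replicate 1 (89.2) or replicate 2 (91.0) alone, within 100 kb (82.9), with q at or below 0.001 (89.2), against random lists of any genes (69.4) and against lists rotated along the gene order (67.2).

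Among blood cells, which the tissue also holds, myeloid genes had a median of 1.54% (percentile 21.9) and 1 of 14 marked promoters, at Coro1a. The percentile was 0.520 within 10 kb and 66.5 within 100 kb. Fcer1g (12.97%), the myeloid master regulator Spi1 (4.13%) and Runx1 (4.04%) were highest and Cd53 had no peak in the replicated list or either replicate. Erythroid genes had a median of 2.61% (percentile 39.3, 5.96 within 10 kb and 23.6 with the peaks of replicate 2) and 5 of 11 marked promoters. Nfe2 (16.7%), the anion exchanger Slc4a1 (9.40%) and the erythropoietin receptor Epor (8.88%) were highest and Rhag had no replicated peak (0.562% in replicate 2). Gata1 (0.652%) and Alas2 (0.442%) lie on chromosome X.

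Targets and feedback inhibitors of developmental signalling pathways lay in densely marked regions. Their 18 genes had a median of 12.1% against 1.24% for random lists (percentile 100), and 17 promoters were marked (11 with peaks covered in both replicates). Smad7 (36.9%, with 41.8% in replicate 1 and 24.0% in replicate 2) and Smad6 (25.6%), both inhibitors of TGF-beta and BMP signalling, and the BMP target Id3 (24.1%) were highest. Axin2, a target of Wnt signalling, lay at 19.2%, Hes1, a target of Notch, at 20.9%, and Hey1 was lowest at 3.19%. Housekeeping genes had a median of 7.97% (percentile 98.5) and 13 of 14 marked promoters, and the percentile was 91.8 with peaks covered in both replicates. Eef2 lay at 17.0%, Rpl13a at 13.4% and Ywhaz at 12.0%. Hprt, on chromosome X, had no replicated peak, and 1.09% of its window and its promoter were marked in replicate 1 alone.

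Hox genes, whose products encode position along the body axis, were densely marked at the anterior end of the HoxA and HoxB clusters. The anterior genes of these clusters, the only anterior genes listed, had a median of 12.7% against 5.02% for random lists (percentile 99.8), with Hoxa5 at 14.1%, Hoxa3 at 13.98%, Hoxa4 at 13.9% and Hoxb6 lowest at 7.89%. Posterior genes, most of them in the HoxC and HoxD clusters, had a median of 4.21% (percentile 54.6), so the lists do not compare the ends of the same clusters. Hoxa10 (8.92%), Hoxa11 (5.58%) and Hoxd10 (4.50%) were highest and Hoxb13 had no replicated peak (0.328% in replicate 1 and 0.208% in replicate 2). A promoter peak was present at 4 of 11 anterior and 5 of 12 posterior genes. The counts were 9 and 7 with the peaks of replicate 1, 4 and 4 with those of replicate 2, and 2 and 2 with peaks covered in both replicates. Neighbouring Hox genes share their windows, so the anterior genes stand for 2 separate regions and the posterior genes for 4.

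Genome-wide, Gse1 on chromosome 8 had the window most covered by H3K4me1 peaks, with 54.8%, followed by Nfix (44.1%), Vgll4 (44.0%), Rara (43.3%), the TGF-beta corepressor Ski (42.5%), the nuclear receptor corepressor Ncor2 (42.0%), the septin Sept9 (41.8%), the basement membrane collagen Col4a1 (41.4%), Dab2ip (41.2%) and the nonmuscle myosin heavy chain Myh9 (40.7%). The 20 highest further held Thra, Bahcc1, Trim8, Rbms1, the receptors Notch1 (38.02%) and Notch2 (35.8%), the alpha-actinins Actn4 and Actn1, Smad7 and Fzr1, down to 35.6%. Gse1 and Nfix also ranked 1 and 2 in replicate 2. Col4a1 ranked 63 there, with 17.9% of its window covered against 51.5% in replicate 1. The median gene had 2.52% of its window covered, and 4659 genes (21.5%) had no peak in it.

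The widest domains, made by joining peaks at most 1 kb apart, were centred in introns. The widest spanned 27095 bp of Myh9 (chromosome 15, 77813679 to 77840773) and held 10 peaks over 90.4% of its length. Replicate 1 covered 92.8% of it and replicate 2 covered 65.8%. It was followed by domains in Bahcc1 (27092 bp), Arhgef17 (26716 bp), Actn4 (25420 bp), Hspg2, which encodes perlecan (23762 bp), Vgll4 (23332 bp), Smad6 (23279 bp), Ets1 (22628 bp), Nfib (22202 bp) and Map4k4 (22174 bp). Of 62328 domains with a median length of 666 bp, 163 reached 10 kb and 40280 held 1 peak. The number that reached 10 kb was 15 with a joining distance of 200 bp, 1208 with 3 kb, 362 with the peaks of replicate 1 and 35 with those of replicate 2. With 200 bp the widest domains lay in Smad7 (20032 bp) and Notch1 (19445 bp). The nearest genes of the 10 widest mostly changed: 2 of the 10 recurred with 200 bp and with the peaks of replicate 2, 3 with 3 kb and with the peaks of replicate 1, and 4 with peaks covered in both replicates. Myh9 was not among the 10 in either replicate's own list, where Sept9 (44423 bp, replicate 1) and Hspg2 (19891 bp, replicate 2) led.

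Of the 5 peaks with the highest signal values, a peak in an intron of the phosphatase gene Ptp4a3 (chromosome 15, 73729753 to 73733149) had a signal value of 11.4, with 12.7 in replicate 1 and 9.10 in replicate 2. A peak in an intron of Ptpn1 (chromosome 2, 167941005 to 167943905) had 11.3. A peak over an exon where Nab2 and Stat6 meet (chromosome 10, 127660627 to 127665694) had 10.9. A peak centred in an intron of Nfix (chromosome 8, 84770905 to 84773881) had 10.7, and it also covers the Nfix start site at 84773396. Another in an intron of Rara (chromosome 11, 98963915 to 98967999), with Gjd3 as the nearest start site, also had 10.7.

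Binding sequences of several transcription factor families were denser in distal peaks than in GC-matched sequence 10 kb away. The palindrome of the nuclear factor I family (TTGGCNNNNNGCCAA) was 5.85 times as dense (95% interval 3.59 to 12.1), found in 185 of 84182 distal peaks and in 17 of 44722 control windows. The MEF2 consensus of muscle genes was 1.83 times as dense (1.63 to 2.06). The CEBP consensus (TTGCGCAA) was 1.92 times as dense (1.21 to 3.30), but its interval included 1 with controls 50 kb away (1.47, 0.892 to 3.02) and with peaks covered in both replicates (1.68, 0.834 to 4.10). GATA (1.297), TEAD (1.28) and ETS (1.23) followed, then SOX (1.17), the CArG box of serum response factor (1.15), NKX2 (1.14) and AP-1 (1.10), all with intervals above 1. Without matching on GC the interval of the CArG box included 1 (1.05, 0.981 to 1.12). FOX sequences were 1.12 times as dense against GC-matched windows and 0.929 times against windows not matched on GC. Bases not marked as repeats made up 87.5% of distal peaks and 72.3% of control windows before weighting on GC. The GC-matched ratio of FOX was 1.34 when bases marked as repeats were left out. On the same measure MEF2 lay at 1.79, CEBP at 1.61, GATA at 1.24, ETS at 1.22 and TEAD at 1.21 times. The CArG box lay at 1.16, SOX at 1.12, NKX2 at 1.09 and AP-1 at 1.05 times. No intervals were computed for these ratios. The intervals of HNF4 (1.09, 0.952 to 1.24) and GLI (1.07, 0.925 to 1.31) included 1, and GLI lay at 0.989 times when bases marked as repeats were left out. They lay above 1 with controls 50 kb away (HNF4 1.18, 1.05 to 1.44, and GLI 1.59, 1.33 to 1.91) and without matching on GC (HNF4 1.10, 1.009 to 1.23, and GLI 1.47, 1.302 to 1.71), and for GLI with the peaks of replicate 1 (1.22, 1.06 to 1.41).

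The core sequence bound by CTCF, the factor of insulators and loop anchors, was 0.626 times as dense in distal peaks as in controls (0.524 to 0.752). RUNX sequences lay at 0.864 times (0.829 to 0.895), and at 1.01 times when bases marked as repeats were left out. TBX sequences (0.890, 0.823 to 0.964) and the neural E-box (0.940, 0.904 to 0.9747) were below their GC-matched controls, and at 1.01 and 1.03 times against windows not matched on GC. Without bases marked as repeats TBX lay at 0.867, the E-box at 0.992 and the CTCF core at 0.555 times. The interval of TBX included 1 with controls 50 kb away (0.946, 0.854 to 1.05), with the peaks of replicate 2 (0.970, 0.880 to 1.08) and with peaks covered in both replicates (0.916, 0.817 to 1.01). Letters of each consensus were rearranged 20 times. No rearrangement reached the ratio of the consensus for NFI, MEF2, GATA, TEAD, ETS or NKX2, 1 did for CEBP, FOX and the CArG box, 3 did for AP-1, 5 did for SOX and for HNF4, and 7 did for GLI. Among the sequences below their controls, 18 of 20 rearrangements lay at or above the ratio of the consensus for the CTCF core and for RUNX, and 16 of 20 for TBX and for the E-box. The lowest rearrangement of the CTCF core lay at 0.429 times. The NFI ratio was 7.27 (4.56 to 13.8) with the peaks of replicate 1. With those of replicate 2 it was 16.4 with a wide interval (7.49 to 107), since 4 control windows held the sequence.

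**Figure D4:**
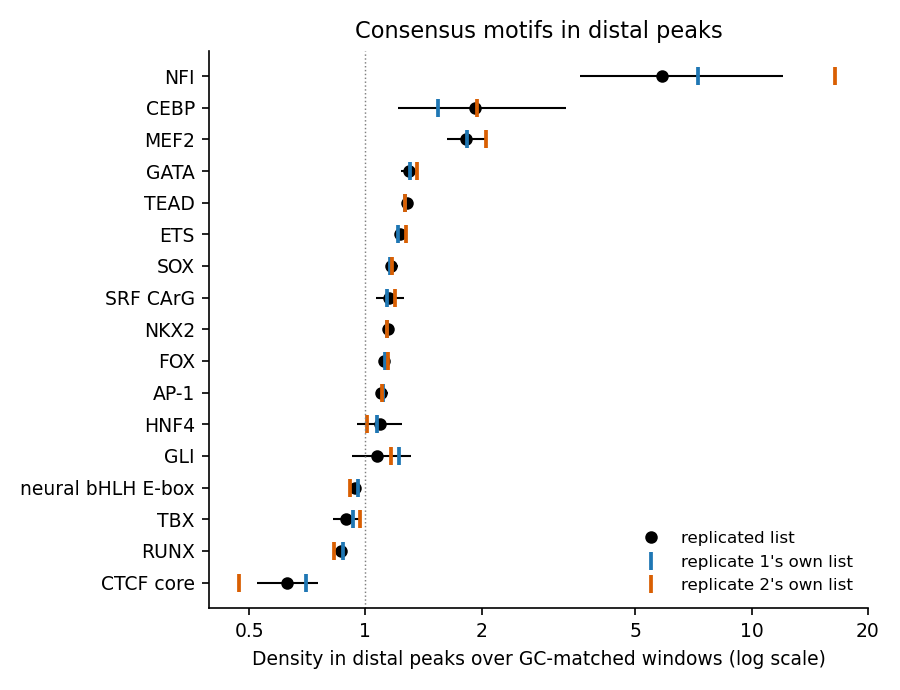
For 17 consensus sequences, the density in distal peaks over the density in GC-matched windows (horizontal log axis) is drawn as black dots with 95% resampling intervals for the replicated list and as blue and orange bars for the lists of replicate 1 and replicate 2, with a dotted line at 1. NFI lies highest at 5.85 and the CTCF core lowest at 0.626.

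Chromosome X held few peaks. They covered 0.137% of chromosome X and a median of 2.48% of an autosome, from 1.69% of chromosome 3 to 3.96% of chromosome 11, so X lay at 0.0552 times the autosomal median. The ratio was 0.0842 with the peaks of replicate 1 and 0.0683 with those of replicate 2. Of the CpG-rich promoters on X, 77 of 235 (32.8%, 27.1 to 39.0) had a peak within 2.5 kb, against 9044 of 9821 (92.1%, 91.5 to 92.6) on the autosomes. Replicate 1 gave 59.1% (52.8 to 65.2) on X and 96.8% on the autosomes, and replicate 2 gave 28.9% (23.5 to 35.0) and 82.2%. X-linked members of the gene lists had 1.59% (Pgk1), 0.652% (Gata1), 0.442% (Alas2), 0.319% (Syn1) and no replicated coverage (Hprt, 1.09% in replicate 1) in their windows. Pools of male and female embryos leave the sexes apart unmeasured, and no list held a peak on chromosome Y.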

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

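The alternatives chosen after seeing the data included the replicated peaks covered in both replicates, the pooled list for the number of peaks and the gene lists rotated along the gene order. The rearranged consensus sequences and the motif ratios without soft-masked bases were also chosen then, and all others were planned. Rotated lists keep neighbours together and are not matched on gene length or start sites. No paired analysis was possible because there is only 1 group. Read depth is unknown, so a peak missing from replicate 2 is not shown to be absent there, and each replicate's own list is a value with no test. Where a cause is not named below, the cause was not tested. With q at or below 0.001, which by construction keeps fewer peaks, 64295 replicated peaks, 117207 peaks of replicate 1 and 8552 of replicate 2 remained, and 41366 replicated peaks were covered in both replicates. The replicates' own lists held 85926 to 178593 peaks. The share of replicate 1 peaks found in replicate 2 was 35.2% with 1 bp, 3.77% with 90% and 3.81% with q at or below 0.001, and that of replicate 2 in replicate 1 was 86.3%, 58.5% and 96.1%. With the top 20000 peaks the shares were 26.6% and 55.9%, and replicate 2 gave 62.0% when ranked by signal value. The correlation was 0.418 with −log10 p. Promoters drawn within 2.5 kb, which by construction take peaks from the other features, gave 4.69-fold for promoters, 1.15-fold for exons and 1.24-fold for introns. Over each replicate's own list the folds ran from 4.89 to 5.85 for promoters, 1.39 to 1.45 for exons, 1.41 to 1.46 for introns and 0.494 to 0.564 for intergenic sequence. Coverage at the start site minus the highest flank was −39.4 points at CpG-rich and −3.31 points at CpG-poor promoters, −20.3 to −11.5 over the replicates' own lists and −11.9 with peaks covered in both.

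Of the 8 lung lists, 5 reached the 95th percentile; 2 did against random lists of any genes, 2 against lists rotated along the gene order and 3 with peaks covered in both replicates. Of the 7 lists of other tissues 1 did (neural genes), as it did within 10 kb and with peaks covered in both replicates, and 0 did within 100 kb, with q at or below 0.001, against random lists of any genes, against rotated lists, or in either replicate's own list (0 to 0). Promoter peaks covered in both replicates were present at 47.1% of lung and 20.7% of other-tissue genes. Domains of at least 10 kb numbered 15 with a joining distance of 200 bp, 1208 with 3 kb, 35 to 362 over the replicates' own lists and 36 with peaks covered in both. The ratio of chromosome X to the autosomes was 0.0683 to 0.0842 over the replicates' own lists and 0.0405 with q at or below 0.001. Without matching on GC, FOX fell to 0.929 times, and the neural E-box (1.03) and TBX (1.01) rose above their controls. Without soft-masked bases RUNX rose to 1.01 times and GLI fell to 0.989 times, and 13 of 17 motifs lay above their controls. Of 168 recomputed percentiles of single gene lists, 81 moved by less than the spread between replicates, 23 rose and 64 fell, and 150 stayed on the same side of the 95th percentile. Of 119 recomputed ratios of single motifs, 54 moved by less than that spread, 35 rose and 30 fell, and 114 stayed on the same side of 1.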

Other observations

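The tests of gaps between peaks, of covered start sites, of the Nfi genes and of the strongest peaks of replicate 2 were chosen after the results they bear on were seen. So were those of rearranged consensus sequences and of ratios without soft-masked bases. The other tests, of chromosome X and of the mix of cells, address patterns already found and were set down before their own values were seen. The CTCF core was less dense than in controls inside distal peaks, where 18 of 20 rearrangements of its letters lay at or above its ratio of 0.626 and the lowest lay at 0.429, so base composition is not excluded for that part. It was denser than in controls between peaks, where rearrangements were not counted. The gaps were 100 to 1000 bp long and lay between neighbouring peaks of the same list. Their centre was over 1 kb from any protein-coding start site. They were not cleared of peaks of the other lists, so they are not shown to be free of called peaks. In the 24267 gaps of the replicated list the CTCF core was 3.97 times as dense as in GC-matched windows (95% interval 2.81 to 6.17), with 200 gaps that held it. The ratio was 2.99 (2.33 to 3.97) in the gaps of replicate 1 and 2.22 (1.38 to 3.37) in those of replicate 2. The excess in gaps was not particular to CTCF: in the same gaps of the replicated list NFI lay at 9.01 times (19 gaps and 2 control windows held it), MEF2 at 1.35 times (1.07 to 1.81), ETS at 1.23, TEAD at 1.15, GATA and NKX2 at 1.14 and FOX at 1.10 times, all with intervals above 1, and TBX was below its controls at 0.775 times. NFI lay at 2.68 times in the gaps of replicate 1 (0.968 to 13.5) and at 5.56 times in those of replicate 2, where 1 control window held it. No biological explanation was tested.

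A peak covered the start site itself in the replicated list and in both replicates at 532 of 21646 genes, 334 of them with CpG-poor promoters. In the neural list 4 of 15 genes were among them (Dlx2, Olig2, Emx2 and Pax6, all transcription factors of the developing nervous system). Random lists matched on CpG class held a mean of 0.330, and 0.0100% of 10000 lists held as many. Hoxd13 and Hoxc10 were among the 12 posterior Hox genes (2.84% of random lists held as many), and Sox2 and Mcidas among the 14 airway genes (5.05%). The alveolar type 1 genes Ager, Hopx, Aqp5 and Sema3e were covered at the start site in the replicated list, where 1.01% of random lists held as many, and none of them was covered in both replicates. In the same list 5 neural (0.05%), 4 posterior Hox (0.370%) and 4 skeletal muscle genes (1.71%) were covered. These percentages were read from 21 lists and were not corrected for that number.

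Chromosome X held few peaks in both replicates. Its lower gene density and higher repeat content account for part of this at most, since X windows matched to autosomal windows on start sites and soft-masked sequence still had 0.136 times their coverage (0.106 to 0.172), against 0.0576 times before matching. Lower signal on X that takes peaks under the calling threshold is a candidate explanation: in replicate 1 the share of X in the weakest of 5 equal classes of peaks was 4.53 times that in the strongest, and the same ratio lay between 0.771 and 1.15 on the autosomes. Whether the signal on X was lower, and by what, stays open, since the lists hold no reads. The single X of male embryos, the inactive X of female embryos and the authors' unstated control and filters were not separated, because both replicates pooled the sexes and no biological explanation was tested.

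Replicate 2 had fewer and weaker peaks than replicate 1. Weaker signal throughout the library stays open: 98.3% of the strongest of 10 equal classes of its peaks was found in replicate 1, but this value was known before the test was chosen and lends no support. A different mix of cells in the pools was tested with the 10 lists of lung and blood cell types. The measure was the share of replicate 1 peaks that overlapped replicate 2 by at least 1 bp, beyond what p and width predicted. For 0 of the 10 lists did it leave the 95% range of random lists. The ranges of random lists were wide (−5.99 to 11.1 points for mesothelium), so smaller differences in makeup stay open. Among all 21 lists neural (15.1 points, range −7.39 to 9.83), hepatocyte (−5.066, limit −5.033) and anterior Hox genes (−7.45, limit −3.85) lay outside. Anterior Hox genes share windows, so their peaks were counted several times, and the range from genes drawn singly does not allow for this. The ranges were not corrected for the number of lists. Sequencing depth and enrichment were not separated, because the lists hold no read counts.

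The NFI palindrome was 5.85 times as dense in distal peaks as in controls. Base composition as the cause is argued against by the rearranged sequences, of which the highest of 20 reached 1.44 times. Their values were known before this test was set down. Repeat copies as the cause are argued against by the ratio without soft-masked bases, which was 5.40 (3.36 to 10.2). The windows of the genes that encode the family were densely covered too, with Nfix at 44.1%, Nfic at 25.5%, Nfib at 25.3% and Nfia at 11.2%, against a median gene at 2.52%. Binding of these factors at some distal elements is a hypothesis that remains untested, and it rests on 185 of 84182 peaks and 17 control windows.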
